A study of Mus musculus with 23 samples.

How the data were processed

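Bulk RNA sequencing of mouse lung was analysed in 23 libraries: wild-type (WT) and Rarres1 knockout (KO) lungs at embryonic day 19.5 (E19.5), 10 months and 18 months, and lung tumours of KO mice at 18 months. The labels give C57BL/6 background, total RNA, a barrier environment, no treatment and male sex for the postnatal mice. They give no sex for the embryos, no time of day and no sequencing batch. Whole-genome profiles of the same series were not analysed here.

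The deposited count table holds expected counts per gene, made by the authors with RSEM; values with decimals occur in every library. The deposited FPKM table holds fragments per kilobase of gene and 1e6 fragments, also made by the authors and rounded to 2 decimals. Per the submitters' processing notes the tools were Trimmomatic 0.36, STAR 2.5.2b and RSEM 1.3.0 with build mm10. All 23 columns of both tables were used, with 24411 genes each. Gene coordinates were taken from GRCm38 annotation, for 24160 genes by RefSeq transcript accession and for 158 by symbol, and 93 genes had no match. Within groups, 28 pairs of libraries were checked for being near copies of each other. Their chi-square per degree of freedom was between 6.72 and 228 over genes with at least 20 counts, so no pair differed by counting error alone.

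Expected counts were rounded to whole numbers. Each comparison was fitted on its own 2 groups with edgeR 4.0.16 in R 4.3.3: TMM scaling, the default filterByExpr filter by group, a robust quasi-likelihood F test, and Benjamini-Hochberg adjustment over all genes tested. Every adjusted p of a gene is from this test unless another tool is named. A gene was called at an adjusted p under 0.05. Fold changes are log2 and carry a prior count of 0.125. Their standard error (SE) was derived from the test, as the absolute fold change over the square root of its F. Group levels are means of TMM-scaled counts per 1e6 counts (CPM) with the standard deviation (SD). Rarres1 levels are CPM of total counts, without TMM scaling. The difference of 2 genotype effects was tested as an interaction in one fit over 4 groups. Tumours and KO non-tumour lungs 1, 3 and 6 carry the same animal codes in their labels and are read as pairs from 3 animals. The correlations of same-number deviations were 0.457, 0.0116 and 0.0614 for these 3 pairs, and 1 of 3 tumours correlated best with its own number. The fixed design has no block, so the results with the animal as a block are printed beside it. In other comparisons the numbers do not pair libraries. The labels say nothing else about the replicates than that they are separate samples, so the p-values measure the spread between these samples.

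Before the data were examined, the comparisons, tests, alternatives, 49 gene lists and the rule for naming genes were fixed. Each list was tested with limma's camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the 47 to 49 lists tested in that comparison. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way, were alternatives. No list call held with an estimated correlation in any of the 8 two-group comparisons: the count was 0 in each. Members of a list were also counted when adjusted over the list alone. A list's level in a library is the mean of log2(CPM + 1) over its genes. Python 3.11.15 with matplotlib 3.10.9 drew the figures.

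The rule names Rarres1 throughout. In each comparison it names up to 8 called genes with the largest rise and up to 8 with the largest fall, with a mean of at least 2 CPM in the higher group and no overlap between the groups. Predicted genes, pseudogenes and receptor segments are skipped, and for each list described up to 4 members with the smallest adjusted p are named. Some genes that the rule names are not reported here. Where a group held 0 reads of a gene, a fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 reads the ratio of pooled reads is given with its exact 95% binomial interval. Intervals and floors cover counting error only.

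Tested on simulated data with the depth and spread of each comparison, the test recovered 47.8% of genes changed 1.5-fold, 82.1% of those changed 2-fold and 87.9% of those changed 4-fold at E19.5. At 10 months it recovered 68.7%, 85.1% and 90.9%, and at 18 months 38.8%, 76.1% and 90.9%. For tumours against KO non-tumour lung it recovered 0%, 41.8% and 86.4%. Unchanged genes made up 10.5% of its calls there, 7.05% at E19.5, 6.86% at 10 months, 9.27% at 18 months and 10.6% for tumours against WT. For the interaction of 18 and 10 months the test recovered 7.46%, 55.2% and 87.9%. The simulated counts were drawn independently for each library. At E19.5 the real libraries gave 144 genes with an unadjusted p under 0.05 in edgeR, where chance gives 765. Rarres1, 53.2-fold lower, was not called there, so the recovered shares may be too high for E19.5. For the interaction of 18 and 10 months 453 genes had an unadjusted p under 0.05 in edgeR, where chance gives 783. The recovered shares may be too high for this interaction too.

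The alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, no count filter, a filter at 1 CPM, one fit over all 23 libraries, limma on log2(FPKM + 1) and on log2(FPKM + 0.1), the replicate number as a block, subsets of the KO lungs, and leaving out each library in turn. Added after seeing the data were the level of the cardiac muscle list as a covariate, leaving out KO non-tumour lungs 6 and 7 together, and the gene lists with each library left out.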

Results

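RNA from mouse lung was sequenced in 23 libraries of 7 groups. WT and KO lungs were collected at E19.5, near birth, with 3 libraries per genotype, and at 10 months with 3 libraries per genotype. At 18 months there were 3 WT lungs, 5 KO non-tumour lungs (numbered 1, 2, 3, 6 and 7 in the labels) and 3 KO lung tumours (numbered 1, 3 and 6). Total counts per library, in units of 1e6 (M), were 23.9 to 28.4 M in WT E19.5, 24.8 to 28.7 M in KO E19.5, 28.1 to 30.2 M in WT at 10 months and 26.8 to 32.0 M in KO at 10 months. At 18 months they were 27.3 to 29.3 M in WT, 23.7 to 46.6 M in KO non-tumour lung and 25.5 to 32.0 M in tumours. Between 17322 and 17895 genes had at least 1 count in a library, and the 10 most abundant genes took 5.60% to 13.7% of the counts.

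Rarres1 (retinoic acid receptor responder 1), a retinoid-inducible gene for a membrane protein related to the carboxypeptidase inhibitor latexin, was read in every library as the measure of genotype. It lies on the minus strand of GRCm38 chromosome 3 from 67478972 to 67515523, with 6 annotated exons. WT lungs held 24 to 64 reads of it each. Its mean was 1.35 ± 0.361 CPM of total counts (without TMM scaling) at E19.5, 1.48 ± 0.263 CPM at 10 months and 2.20 ± 0.131 CPM at 18 months (SD, n = 3 each). KO lungs held 2 reads against 105 in WT at E19.5, which makes WT 53.2-fold higher (95% counting interval 14.4 to 445). They held 0 reads at 10 months against 130 in WT, and 0 reads in non-tumour lung at 18 months against 187 in WT, so WT was at least 43.1-fold and at least 109-fold higher. The tumours held 1 read, 186-fold below WT (33.0 to 7397). In all 23 libraries the Rarres1 reads went with the genotype label. The test called it at 10 months (adjusted p = 0.00260; DESeq2 did not call it there), at 18 months (0.00719; 0.0523 without WT 1, 0.0595 without WT 2 and 0.0559 without WT 3) and in tumours against WT (0.00571; 0.0514 without WT 2 and 0.0665 without WT 3). In WT its level did not pass the test between 10 and 18 months (log2 fold change 0.57 ± 0.21, adjusted p = 0.891) or between E19.5 and 10 months (0.18 ± 0.30, adjusted p = 0.616).

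**Figure D1:**
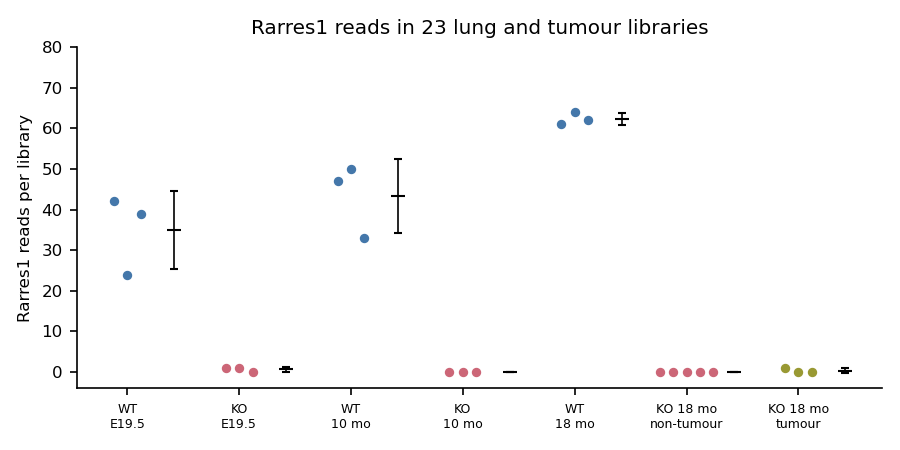
Rarres1 reads in each of the 23 libraries, by group, with the mean and SD at the right of each group. The WT libraries hold 24 to 64 reads each, and each KO group holds at most 2 reads in total.

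The comparison of KO with WT at E19.5 asks what loss of Rarres1 does to the lung at the end of gestation. No gene passed the test in these 6 libraries, and Rarres1 came closest. It stood 53.2-fold lower by pooled reads (n = 3 per group) with an adjusted p of 0.122 in the edgeR quasi-likelihood test, the lowest of the comparison. Of 15307 genes tested, 0 were called, and 144 had an unadjusted p under 0.05 where chance gives 765. DESeq2 called Rarres1 and the predicted gene Gm14548, and so did limma on log2(FPKM + 0.1), 2 genes each; limma on log2(FPKM + 1) called 0 and a fit over all 23 libraries called Rarres1, 1 gene. The groups did not overlap in 759 genes (4.96%), against 10% by chance.

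Gene lists did pass at E19.5, 4 higher and 14 lower in KO. Interferon response genes were lower as a group, with a median log2 fold change of −0.44 (adjusted p = 1.61e-09, and 0.71 with an estimated correlation). Stat2, which relays interferon signals to the nucleus, stood at −0.39 ± 0.20 and Mx1, an antiviral GTPase, at −0.72 ± 0.48 (0 of 21 members tested were called, and 0 adjusted over the list alone). DNA replication genes were lower (adjusted p = 1.57e-08, and 0.71 with an estimated correlation), with the helicase subunit Mcm4 at −0.23 ± 0.12 and 0 of 20 members called in either way. The genotypes overlapped in both list levels. Interferon response lay at 3.83, 4.32 and 4.72 in the WT embryos and at 4.43, 3.78 and 3.45 in the KO embryos. DNA replication lay at 3.83, 4.20 and 3.87 in WT and at 3.72, 4.00 and 3.56 in KO. Hepatocyte genes were higher (adjusted p = 4.63e-05, and 0.71 with an estimated correlation) with 3 members tested and 0 called, among them the plasma proteins Ahsg at 1.35 ± 0.48 and Alb at 1.17 ± 0.62. Markers of basal and squamous cells were lower (adjusted p = 0.000155, and 0.71 with an estimated correlation) with 0 members called: the oesophageal-type keratins Krt13 and Krt4 stood at −7.91 ± 3.58 and −6.93 ± 3.21. That list lay at 5.31 in WT embryo 3 and at most 1.36 in the other 5 embryos, in log2(CPM + 1). Skeletal muscle markers were lower (adjusted p = 0.0288, and 0.812 with an estimated correlation); without WT embryo 3, whose level was 4.02, they were higher in KO (adjusted p = 0.00146). Single embryos carried other calls too: the basal and squamous list was lost without WT embryo 3 (adjusted p = 0.722), the DNA replication list without WT embryo 2 (0.108) and the skeletal muscle list without KO embryo 2 (0.543) or 3 (0.188). Without KO embryo 3, 16 lists passed, 8 of them among the 18, and without WT embryo 3, 16 and 9.

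At 10 months the comparison of KO with WT asks what the loss does in the adult lung. Rarres1 aside, genes of the circadian clock held the largest rise and the largest falls among the genes that the naming rule gives. Dbp, a clock output transcription factor on chromosome 7 (45705100 to 45710203), rose from 14.8 ± 1.29 to 183 ± 31.3 CPM (SD, n = 3 each), a log2 fold change of 3.62 ± 0.14 (adjusted p = 8.29e-05). Arntl (chromosome 7, 113178471 to 113314126), which encodes the clock activator BMAL, fell from 36.8 ± 3.02 to 6.21 ± 1.39 CPM, and its relative Npas2, a partner of BMAL, fell from 15.7 ± 1.15 to 2.39 ± 0.421 CPM. Genes for heat shock proteins fell with them: Hsph1, a co-chaperone of Hsp70 proteins, fell from 104 ± 12.6 to 31.9 ± 2.84 CPM.

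In all, 233 of 15324 genes were called at 10 months, 88 higher and 145 lower in KO, of which 34 changed at least 2-fold (15 higher, 19 lower). Of the 17 clock genes 7 rose, 3 fell and 7 did not pass; adjusted over the list alone 11 rose and 4 fell. The list passed as higher with a median of 1.17 (adjusted p = 3.11e-26, and 0.0738 with an estimated correlation). Besides Dbp, the risers included the other output factor Hlf (1.79 ± 0.12), the period gene Per3 (1.73 ± 0.10), and the repressors Bhlhe41 (1.59 ± 0.14), Ciart (1.69 ± 0.27) and Nr1d2 (1.28 ± 0.09). Npas2 stood at −2.73 ± 0.14 and Arntl at −2.58 ± 0.16, with adjusted p values of 8.29e-05 and 0.000573. Outside the clock list, the tetraspanin gene Tspan4 (1.56 ± 0.11) and Rasd2, a small GTPase (1.43 ± 0.14), were among the 8 largest rises that the naming rule gives. The remaining falls that it gives, from at least 2 CPM and with no overlap, were Fam124b (−2.14 ± 0.34), the nuclear receptor Nr4a3 (−1.77 ± 0.25), Tmem171 (−1.53 ± 0.21), the vasopressin receptor Avpr1a (2.84-fold lower) and the small GTPase Rasl11a (−1.30 ± 0.16).

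Of 11 heat shock genes 6 fell at 10 months (7 adjusted over the list alone), and the list passed as lower with a median of −0.51 (adjusted p = 7.42e-24, and 0.0738 with an estimated correlation). The abundant chaperones Hspa8 (−0.79 ± 0.09), Hsp90aa1 (−0.87 ± 0.10) and Dnaja1 (−0.63 ± 0.08) were among them. Cholesterol synthesis genes were higher, with 19 of 19 members tested above 0 and a median of 0.30 (adjusted p = 5.88e-10, and 0.826 with an estimated correlation). Of these Lss, the lanosterol synthase, rose (0.49 ± 0.08, adjusted p = 0.0179), and 9 passed when adjusted over the list alone. Smooth muscle genes were lower (adjusted p = 0.000119, and 0.826 with an estimated correlation) with 0 of 10 called and 6 adjusted over the list alone; the contractile gene Cnn1 stood at −0.54 ± 0.12. Ciliated cell genes were lower (adjusted p = 0.000509, and 0.866 with an estimated correlation): the dynein gene Dnah5 fell (−0.39 ± 0.06, adjusted p = 0.0224), and 5 of 16 passed when adjusted over the list alone. Matrix genes were lower (adjusted p = 0.000609, and 0.826 with an estimated correlation) with 0 of 17 called in either way, elastin (Eln) standing at −1.57 ± 0.30 with an adjusted p of 0.102. The 3 other lists that passed were alveolar macrophages, higher (adjusted p = 0.00391, and 0.866 with an estimated correlation), club cells, lower (0.00795, and 0.826 with an estimated correlation) and immediate early genes, higher (0.041, and 0.866 with an estimated correlation). Club cell levels overlapped, at 8.56, 6.96 and 7.44 in WT and 6.68, 8.21 and 7.26 in KO. Those of alveolar macrophages did too, at 4.99, 5.41 and 4.96 in WT and 5.44, 5.37 and 5.27 in KO. Immediate early genes lay at 5.97, 5.62 and 5.13 in KO against 5.09 to 5.43 in WT. Retinoid genes did not pass (adjusted p = 0.811). The heart muscle markers, which varied from 2.33 to 5.76 between these 6 lungs, did not pass either (adjusted p = 0.757). Without KO 2, 15 lists passed in place of 9, and without KO 1, 7 did. Over the libraries left out in turn, as few as 6 of the 9 stayed called.

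The 10-month count moved with single libraries: the test on 5 libraries called 66 genes without KO 1, 88 without WT 3, 109 without WT 2, 127 without KO 3, 134 without WT 1 and 205 without KO 2; a fit over all 23 libraries called 41 and DESeq2 594. Named calls were lost without 1 library for Ciart and Fam124b (any WT or KO 1; adjusted p 0.107 to 0.169 and 0.114 to 0.205), Avpr1a (the same 4; 0.0523 for the lowest), Nr4a3 (WT 1, KO 1 or KO 3; 0.0572 to 0.0934), Rasl11a (WT 3 or KO 1; 0.0637 and 0.0657) and Tmem171 (WT 3; 0.0525). The groups did not overlap in 3787 genes (24.7%), against 10% by chance.

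**Figure D2:**
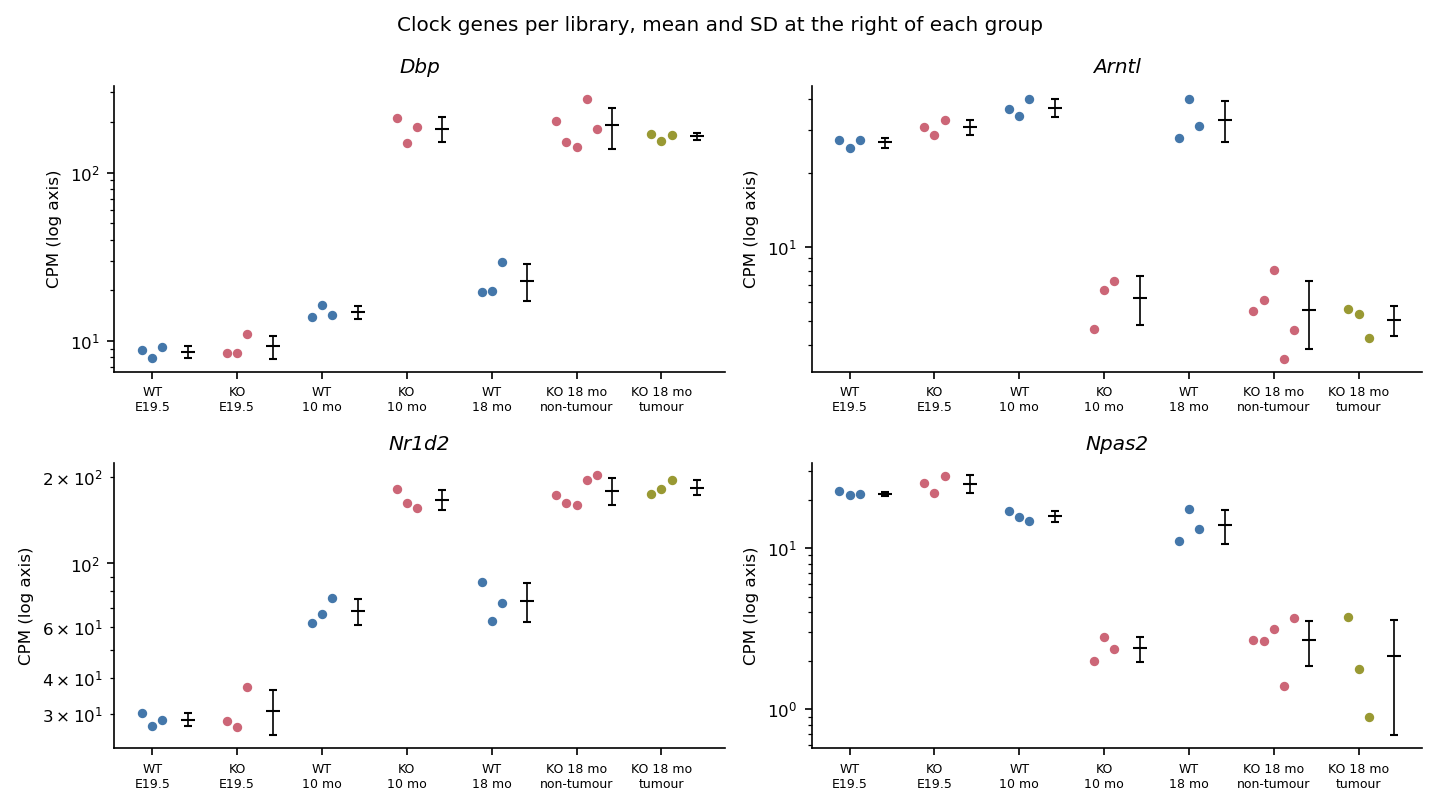
Level of circadian clock genes in CPM for each library, on a log axis, by group, with the mean and SD at the right of each group. In adult lungs Dbp averages 183 and 191 CPM in KO against 14.8 and 22.9 in WT, while Arntl averages 6.21 and 5.57 against 36.8 and 32.9.

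At 18 months the KO non-tumour lungs were compared with WT lungs, which asks what differs in aged lung beside the tumours. Rarres1 aside, clock genes again held the largest rise and the largest falls among the genes that the naming rule gives. Dbp rose from 22.9 ± 5.64 CPM in WT (SD, n = 3) to 191 ± 52.5 CPM in KO (n = 5), a log2 fold change of 3.06 ± 0.25 (adjusted p = 0.00274), and Arntl fell from 32.9 ± 6.20 to 5.57 ± 1.72 CPM (−2.56 ± 0.22, adjusted p = 0.00274). Rasl11a fell from 25.3 ± 0.602 to 8.97 ± 1.44 CPM (2.83-fold, adjusted p = 0.00274). Heart muscle markers were lower in the KO lungs as a group, with list levels of 1.89 to 3.47 against 4.07 to 4.23 in WT.

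Of 15463 genes, 12 were called at 18 months, 7 higher and 5 lower in KO. Besides Rarres1, Dbp, Arntl and Rasl11a they were the clock genes Hlf (1.48 ± 0.16), Nr1d2 (1.26 ± 0.13), Nr1d1 (1.05 ± 0.12), Bhlhe41 (1.64 ± 0.20) and Npas2 (−2.36 ± 0.26), with Tspan4 (1.24 ± 0.15), the zinc finger gene Zfp346 (0.73 ± 0.10) and the predicted gene 5430416O09Rik (−1.24 ± 0.17), the last outside the naming rule. Of the 17 clock genes 5 rose, 2 fell and 10 did not pass; adjusted over the list alone 9 rose and 4 fell (list adjusted p = 1.56e-14, and 0.184 with an estimated correlation).

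The other lists that passed at 18 months did so with 0 members called. Of the heart muscle genes, lower as a group (adjusted p = 1.11e-26, and 0.22 with an estimated correlation), 10 of 13 passed adjusted over the list alone, and the atrial myosin light chains Myl7 and Myl4 stood at −2.38 ± 0.44 and −2.13 ± 0.41. Mitosis genes were higher, 23 of 24 above 0 (adjusted p = 4.9e-11, and 0.471 with an estimated correlation), and 0 passed adjusted over the list alone; the survivin gene Birc5 stood at 1.25 ± 0.32. Interferon response genes were higher, 22 of 23 above 0 (adjusted p = 6.1e-08, and 0.471 with an estimated correlation), with the chemokine Cxcl10 at 1.79 ± 0.63. Markers of T and NK cells were higher, 16 of 16 above 0 (adjusted p = 1.9e-05, and 0.505 with an estimated correlation), with the T cell receptor subunit gene Cd3e at 0.88 ± 0.30. Alveolar macrophage markers were higher (adjusted p = 2.99e-05, and 0.505 with an estimated correlation) with 3 of 14 passing adjusted over the list alone, among them the mannose receptor Mrc1 at 0.50 ± 0.11. Genes of MHC class II presentation were higher, 9 of 9 above 0 (adjusted p = 0.000481, and 0.505 with an estimated correlation), and club cell genes were lower (adjusted p = 3.83e-05, and 0.471 with an estimated correlation). KO lung 2 lay within the WT range of the list level for mitosis (2.22 against 1.89 to 2.26), interferon response (4.44 against 4.22 to 4.45), T and NK cells (2.69 against 2.59 to 3.15) and MHC class II (6.89 against 6.86 to 7.02), while lungs 1 and 6 lay highest for mitosis (2.93 and 2.87). KO lung 7 lay below the WT lungs for alveolar macrophages (5.00 against 5.05 to 5.34). For club cells, KO lungs 1 and 7 (7.16 and 6.96) lay within the WT range of 6.67 to 7.75. KO lungs 2, 3 and 6 lay below that range (6.39, 6.23 and 6.14). The chromosomal neighbours of Rarres1 were lower (adjusted p = 0.0363, and 0.471 with an estimated correlation), with Schip1 at −0.52 ± 0.13. In all, 11 lists passed as higher and 12 as lower.

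DESeq2 called 154 genes at 18 months (62 higher and 92 lower), the 12 among them. An unadjusted p under 0.05 in edgeR was found for 1243 genes, where chance gives 773. Without WT 2 or WT 3, 3 genes remained called (Dbp, Arntl and Rasl11a), without WT 1, 6, and without KO 7, 26; without KO 6 and 7 together the count was 42. The other calls were lost without WT 2 or WT 3, and several without WT 1 too: Bhlhe41 (0.0997 to 0.131), Nr1d1 (0.0559 to 0.1003), Tspan4 (0.0618 to 0.131), Hlf (0.0559 and 0.0589), Npas2 (0.0559 and 0.0595), Nr1d2 (0.0595 and 0.0653) and Zfp346 (0.0574 to 0.306, also without KO 1, 2 or 7). The groups did not overlap in 1039 genes (6.72%), against 3.57% by chance.

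The effects at the 2 adult ages shared genes. Called in both, with no library in common, were 6 genes higher in KO (Dbp, Hlf, Nr1d2, Bhlhe41, Tspan4 and Zfp346; 0.0404 expected, exact hypergeometric test, p = 2.17e-13). Besides Rarres1, 4 were lower in both (Arntl, Npas2, Rasl11a and 5430416O09Rik; 0.0375 expected, exact hypergeometric test, p = 7.44e-09). Both tests take genes as independent, while several of these belong to the clock list, so the p-values may be too small. Of 231 genes called at 10 months and measured at 18 months, 215 (93.1%) had the same sign there, and 135 of 230 (58.7%) at E19.5. Across 15238 genes, which are not independent replicates, the fold changes at 10 and 18 months correlated with r = 0.378 (rho = 0.392). The difference between the effects at 10 and 18 months passed for 0 genes in edgeR. There 453 genes had an unadjusted p under 0.05, where chance gives 783. DESeq2 called 1 gene for this difference, the predicted gene Gm7120. Between 10 months and E19.5 the effect differed for 25 genes, 10 upward and 15 downward, led by Dbp (3.53 ± 0.20), Npas2 (−2.93 ± 0.18) and Arntl (−2.77 ± 0.18). Within 10 Mb of Rarres1, 0 of 54, 57 and 57 tested genes were called at the 3 ages by edgeR, and 0, 2 and 2 had an unadjusted p under 0.01 (Mlf1 and Schip1 at 10 months, Gm6634 and Schip1 at 18 months, chosen after their values were seen).

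The tumours were compared with the KO non-tumour lungs of the same age, which asks how tumour tissue differs from non-tumour lung of KO mice. The tumours carried more of the alveolar type 2 cell program and less of the ciliated cell, smooth muscle and fibroblast ones. Club cell genes were lower in tumours 3 and 6, and endothelial genes in tumours 1 and 3. The remaining tumour lay within the range of the lungs for each of these 2 list levels. Of 16 type 2 genes 15 rose: Slc34a2, the phosphate carrier of these surfactant-making cells, rose from 2005 to 6425 CPM (log2 fold change 1.68 ± 0.19; n = 3 tumours and 5 lungs), and Fasn, the fatty acid synthase, rose by 1.56 ± 0.16 (adjusted p = 0.00131). Of 16 ciliated cell genes 15 fell, among them Tekt1, a protein of the ciliary axoneme (−1.53 ± 0.22). Ligands of the EGF receptor and targets of MAPK signalling rose as a group: Ereg, an EGF receptor ligand on chromosome 5 (91074617 to 91093649), went from 0.295 ± 0.132 to 40.6 ± 42.0 CPM (7.13 ± 0.74, adjusted p = 0.00136).

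Of 15459 genes, 2134 were called, 1113 higher and 1021 lower in tumours, and 1219 changed at least 2-fold (582 and 637). The largest rises by the naming rule (at least 2 CPM, no overlap) included Cldn2, a pore-forming claudin (128-fold, to 88.4 ± 68.7 CPM, adjusted p = 0.000963) and Awat1, a wax synthase (0.0800 ± 0.117 to a mean of 10.8 CPM; 7.17 ± 1.18). Single tumours carried much of this: Awat1 stood at 28.2, 1.54 and 2.79 CPM in tumours 1, 3 and 6 (4.89 without tumour 1, 8.54 without lung 6), Ereg at 9.35, 88.4 and 24.1 CPM (5.86 without tumour 3) and Cldn2 at 84.0, 159 and 22.0 CPM (6.24 without tumour 3). A further 4 had at most 3 reads in all non-tumour lungs together. Gja3, a connexin, was 465-fold higher in tumours (159 to 2261), Gkn2, a gastrokine, 667-fold (119 to 26424), Cyp21a1, a steroid hydroxylase, 468-fold (83.2 to 18538), and Cyp2c40, a cytochrome P450, at least 133-fold. Tumour 3 held 67.7% of the Gkn2 reads (317-fold without it) and tumour 1 held 71.5% of the Cyp2c40 reads (at least 61.0-fold without it). The largest falls by that rule were in genes of fat tissue, Cfd (−5.08 ± 1.00; −8.37 without tumour 3), an adipocyte protease also called adipsin, and the carbonic anhydrase Car3 (−4.80 ± 0.85), then Asgr1 (−3.06 ± 0.50), Slurp1 (−2.93 ± 0.64), Tbata (−2.76 ± 0.26), Itgad (−2.76 ± 0.69) and Entpd8 (−2.72 ± 0.77; −3.52 without tumour 3). Sult1d1, a sulfotransferase, fell from 16.0 ± 2.89 to 2.11 ± 0.463 CPM (−2.93 ± 0.25, adjusted p = 0.0007).

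Type 2 cell genes passed as a list (adjusted p = 9.94e-23, and 0.13 with an estimated correlation), with 16 of 16 passing adjusted over the list alone and Il33 (1.91 ± 0.23) and Lpcat1 (1.63 ± 0.22) among them. Ciliated cell genes passed as lower (1.74e-18, and 0.212 with an estimated correlation), with 16 passing adjusted over the list alone. Of 21 EGF receptor and MAPK genes 13 rose (adjusted over the list alone 15 rose and 1 fell; list adjusted p = 4.08e-11, and 0.241 with an estimated correlation), including the transcription factor Etv4 (4.97 ± 0.50), the feedback inhibitor Spred1 (1.34 ± 0.18) and the cyclin Ccnd1 (1.21 ± 0.17). Of 16 epithelial junction genes 9 rose, Epcam by 1.11 ± 0.21 (list adjusted p = 2.05e-05, and 0.43 with an estimated correlation), and 9 passed adjusted over the list alone. Of 10 club cell genes 5 fell, among them the secretoglobins Scgb1a1 (−1.74 ± 0.32) and Scgb3a2 (−2.04 ± 0.33) and the cytochrome Cyp2f2 (−1.64 ± 0.20), with 5 also adjusted over the list alone (list adjusted p = 2.37e-05, and 0.212 with an estimated correlation). Of 5 hepatocyte genes tested 4 rose, including the plasma proteins Fga (6.55 ± 0.51) and Alb (4.32 ± 0.56; 11.3-fold without tumour 3), with 4 adjusted over the list alone (list adjusted p = 1.04e-05, and 0.13 with an estimated correlation).

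Smooth muscle, endothelial and fibroblast lists fell in the tumours, while the extracellular matrix list did not pass (11 of 17 genes above 0, median 0.09; adjusted p = 0.451, and 0.806 with an estimated correlation). Smooth muscle genes passed as lower with 4 of 10 called (7 adjusted over the list alone; adjusted p = 9.45e-06, and 0.37 with an estimated correlation), led by Cnn1 (−2.07 ± 0.22). Endothelial genes passed as lower with 4 of 16 called (11 adjusted over the list alone; adjusted p = 9.45e-06, and 0.457 with an estimated correlation), among them Ramp2 (−1.18 ± 0.31). Their list level was at most 7.16 in tumours 1 and 3 and 8.31 in tumour 6, against 8.24 to 8.64 in the 5 lungs. Fibroblast genes passed as lower with 4 of 13 called (6 adjusted over the list alone; adjusted p = 1.57e-05, and 0.241 with an estimated correlation), Inmt falling by 1.46 ± 0.22 on the log2 scale. Adipocyte markers (5 of 10 fell, 8 adjusted over the list alone; list adjusted p = 3e-05, and 0.241 with an estimated correlation) and mesothelial markers (4 of 7 fell, 7 adjusted over the list alone; list adjusted p = 0.000436, and 0.457 with an estimated correlation), which mark fat and pleura beside the lung tissue, were lower too.

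**Figure D3:**
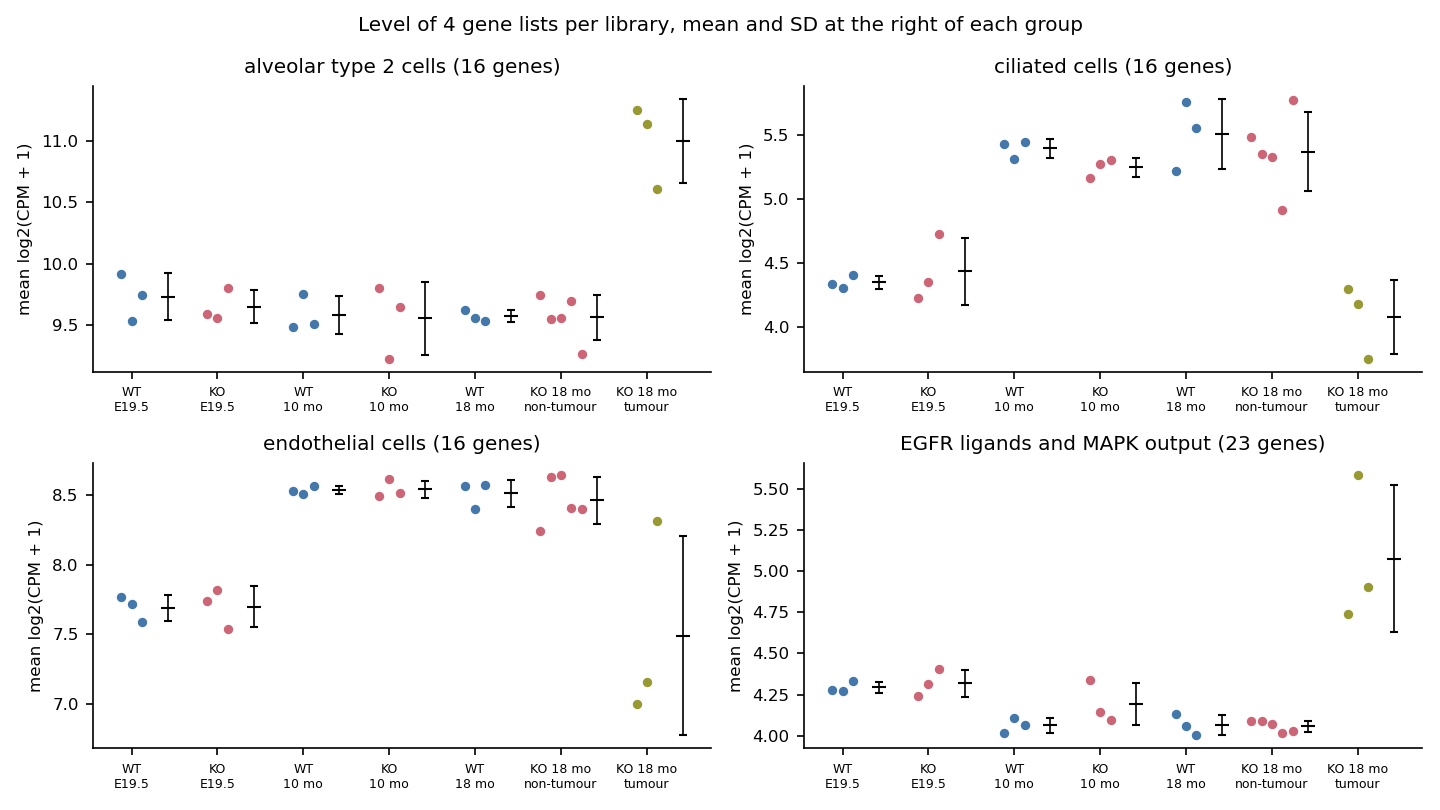
Mean log2(CPM + 1) of the genes of 4 lists in each library, by group, with the mean and SD at the right of each group. The 3 tumours lie above every other library for alveolar type 2 and EGF receptor and MAPK genes, and tumour 6 lies at 8.31 for endothelial genes against at most 7.16 in the other tumours.

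Metabolic and retinoid genes also differed between the tumours and the lungs. Of 15 fatty acid synthesis genes 5 rose and 2 fell (6 and 2 adjusted over the list alone; list adjusted p = 0.00717, and 0.212 with an estimated correlation), with the desaturase Scd1 at 1.99 ± 0.29, malic enzyme Me1 at 1.94 ± 0.27, the carboxylase Acaca at 0.89 ± 0.12 and the acyltransferase Dgat2 at −0.67 ± 0.13. Of 14 glycolysis genes 5 rose, including Hk2 (1.20 ± 0.15) and Ldha (1.20 ± 0.23), with 5 adjusted over the list alone (list adjusted p = 0.0012, and 0.474 with an estimated correlation). Of 19 cholesterol synthesis genes 5 rose, and 8 passed adjusted over the list alone (list adjusted p = 0.000456, and 0.464 with an estimated correlation). Of 17 p53 targets 7 rose and 1 fell (7 and 2 adjusted over the list alone; list adjusted p = 0.00234, and 0.224 with an estimated correlation), with the stress cytokine Gdf15 at 2.37 ± 0.42 (1.70 without tumour 3) and Zmat3 at 0.87 ± 0.11. Of 16 retinoid genes 1 rose and 3 fell (1 and 4 adjusted over the list alone; list adjusted p = 0.00438, and 0.212 with an estimated correlation). Among them the retinol carrier Rbp4 stood at 1.61 ± 0.36, the retinaldehyde dehydrogenase Aldh1a1 at −1.39 ± 0.26 and the chemerin gene Rarres2 at −1.09 ± 0.23. Mitosis genes passed as higher with 0 of 24 called in either way (adjusted p = 0.00833, and 0.67 with an estimated correlation). The clock list did not pass (adjusted p = 0.381), with 0 of 17 called. In all, 10 lists passed as higher and 13 as lower.

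The number of genes called against KO lung depended on single libraries: 1074 without tumour 3, 1150 without KO lung 2, 1255 without KO lung 3, 1288 without tumour 1, 1330 without KO lung 1 and 4066 without tumour 6, while DESeq2 called 3410. On log2(FPKM + 1) limma called 784 higher and 1305 lower, and on log2(FPKM + 0.1) 814 and 1447, against 1113 and 1021. The calls of Entpd8 (all but KO lung 6; adjusted p 0.0601 to 0.139), Itgad (tumours 1 and 3, KO lungs 1, 2 and 7; 0.0577 to 0.0955) and Slurp1 (tumour 1; 0.0510) were lost without the libraries named. The groups did not overlap in 3235 genes (20.9%), against 3.57% by chance.

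Tumours and lungs 1, 3 and 6 are read as pairs by the numbers in their sample codes. With the animal as a block edgeR called 146 genes, 84 higher and 62 lower, 145 of them among the 2134, and 135 with the 3 tumours and their 3 matched lungs alone. Of the 16 genes that the rule for large changes gives 9 kept their call with the block, and Cyp2c40 (adjusted p = 0.0521), Awat1 (0.0700), Cfd (0.106), Car3 (0.0586), Asgr1 (0.0762), Itgad (0.160) and Entpd8 (0.0730) did not. Of the list genes named above Il33, Lpcat1, Tekt1, Ereg, Scgb3a2, Fga, Alb, Cnn1 and Hk2 kept theirs. Those of Fasn (0.0565), Slc34a2 (0.0719), Etv4 (0.0520), Spred1 (0.0520), Ccnd1 (0.0720), Epcam (0.114), Scgb1a1 (0.122), Cyp2f2 (0.0720), Ramp2 (0.0774), Inmt (0.0609), Scd1 (0.0675), Me1 (0.0719), Acaca (0.0609), Dgat2 (0.107), Ldha (0.126), Gdf15 (0.0887), Zmat3 (0.0545), Rbp4 (0.159), Aldh1a1 (0.0826) and Rarres2 (0.0520) were lost. With the block 26 lists passed, 21 of them among the 23; the mitosis list (0.0563) and the MHC class II list (0.153) were lost. Numbers of called list members above are without the block.

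Against WT lungs of the same age the tumours again differed in ciliated and type 2 cell genes, and here the clock list passed too. Meg3, a long noncoding RNA of the imprinted cluster on chromosome 12 (109540996 to 109571729), rose from 3.24 ± 0.575 to 505 ± 210 CPM (log2 fold change 7.28 ± 0.40, n = 3 per group, adjusted p = 0.00371). Fga, the fibrinogen alpha chain, rose from 0.130 ± 0.0529 to 41.8 ± 17.0 CPM (8.27 ± 0.48, adjusted p = 0.00371). All 16 ciliated cell genes fell (list adjusted p = 4.38e-18, and 0.39 with an estimated correlation), and 14 of 16 type 2 cell genes rose (8.36e-14, and 0.39 with an estimated correlation), each with 16 adjusted over the list alone. Of 17 clock genes 7 rose and 3 fell, the same counts adjusted over the list alone (list adjusted p = 0.0105, and 0.39 with an estimated correlation), with Dbp at 2.84 ± 0.18 and Arntl at −2.70 ± 0.19.

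In this comparison 2358 of 15346 genes were called, 1207 higher and 1151 lower, 1424 of them at least 2-fold. Ereg rose by 7.55 ± 1.12 (6.25 without tumour 3) and Sult1d1 fell by 3.36 ± 0.30 on the log2 scale. Of the genes with at most 2 reads in the WT lungs, Awat1 was 470-fold higher in tumours (130 to 3885), Gkn2 382-fold (68.2 to 15146), Cyp21a1 268-fold (47.7 to 10626), Sprr2a1, a cornified envelope gene, 189-fold (51.9 to 1564) and Cyp2c40 at least 76.3-fold. Tumour 1 held 88.2% of the Awat1 reads (88.8-fold without it), 77.9% of those of Sprr2a1 (67.0-fold) and 71.5% of those of Cyp2c40 (at least 35.0-fold), and tumour 3 held 67.7% of those of Gkn2 (182-fold). Further large falls were in Cfd (−5.82 ± 0.91; −9.11 without tumour 3), Car3 (−5.49 ± 0.69), Asgr1 (−3.57 ± 0.60) and Kcnj3, a potassium channel gene (−3.38 ± 0.82; −4.43 without tumour 6). The muscle genes Sln (−3.72 ± 0.87) and Smpx (−3.70 ± 0.74) fell too (−4.53 and −4.60 without tumour 6), and of 13 heart muscle genes 5 fell and Myh7 rose (3.00 ± 0.66; 2.06 without tumour 3), with 9 and 1 adjusted over the list alone (list adjusted p = 5.55e-05, and 0.435 with an estimated correlation). Of 24 mitosis genes 7 rose, Plk1 by 1.61 ± 0.25, and 19 adjusted over the list alone (list adjusted p = 8.52e-08, and 0.435 with an estimated correlation). Of 9 genes of MHC class II presentation 7 rose, among them the master regulator Ciita (1.38 ± 0.17) and Cd74 (1.32 ± 0.20), with 7 adjusted over the list alone (list adjusted p = 2.27e-05, and 0.435 with an estimated correlation). Of 16 retinoid genes 6 fell, led by Rarres2 (−1.35 ± 0.12), with 7 down and 1 up adjusted over the list alone (list adjusted p = 0.00035, and 0.39 with an estimated correlation). In all, 14 lists passed as higher and 13 as lower.

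This count rested on the 3 WT lungs: the test called 3 genes without WT 3 (Dbp, the fibrinogen gene Fgg and Rasd2), 11 without WT 2 and 504 without WT 1, but 5722 without tumour 6, while DESeq2 called 4182. Of the genes named here from this comparison every call was lost without WT 3 except those of Dbp, Fgg and Rasd2. Meg3 and Fga then had an adjusted p of 0.0542, and the other large changes 0.0514 to 0.144 without the library concerned. These libraries were WT 1 to 3, tumour 1 for Kcnj3 and Sln, and tumour 3 for Cyp2c40. The groups did not overlap in 6560 genes (42.7%), against 10% by chance.

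Between 10 and 18 months the lungs of each genotype were compared to describe ageing. In WT 0 of 15321 genes were called by edgeR and 17 by DESeq2, yet several lists shifted together. An unadjusted p under 0.05 in edgeR was found for 833 genes, where chance gives 766. Smooth muscle genes were lower at 18 months (median −0.28, adjusted p = 8.21e-13, and 0.449 with an estimated correlation), Cnn1 standing at −0.72 ± 0.11 (n = 3 per group), with 6 of 10 adjusted over the list alone. Heat shock genes were lower (adjusted p = 6.17e-10, and 0.449 with an estimated correlation; 5 of 11 adjusted over the list alone), and matrix genes were lower (9.12e-05, and 0.449 with an estimated correlation), with collagen Col3a1 at −0.33 ± 0.09. Cholesterol synthesis genes were higher (2.42e-09, and 0.592 with an estimated correlation), as were p53 targets (6.76e-05, and 0.391 with an estimated correlation), 3 of 17 adjusted over the list alone, with Phlda3 at 0.39 ± 0.07 and Gdf15 at 0.78 ± 0.21. WT 1 of 18 months did not share all of these shifts. Its list level was 6.85 for heat shock (6.81 to 6.92 at 10 months), 7.01 for matrix (6.97 to 7.21) and 5.34 for cholesterol synthesis (5.31 to 5.35). For smooth muscle and p53 targets each 18-month WT lung lay outside the 10-month range. In all 9 lists passed as higher and 9 as lower, and 9 passed without WT 3 of 18 months. Without WT 1 of 18 months 10 genes were called, without WT 1 of 10 months 3 and without WT 2 of 10 months 2 (Cnn1 and the keratin Krt15).

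In KO lungs 0 of 15455 genes were called between 10 and 18 months by edgeR and 11 by DESeq2, with n = 3 and 5. An unadjusted p under 0.05 in edgeR was found for 782 genes, where chance gives 773. Mitosis genes were higher at 18 months, 24 of 24 above 0 (median 0.55, adjusted p = 7.21e-13, and 0.433 with an estimated correlation), with the proliferation marker Mki67 at 0.79 ± 0.22. Markers of T and NK cells were higher (adjusted p = 3.01e-09, and 0.415 with an estimated correlation), with Cd3e at 1.38 ± 0.31, and so were interferon response genes (4.45e-08, and 0.415 with an estimated correlation) and p53 targets (0.00856, and 0.415 with an estimated correlation), with Gdf15 at 1.10 ± 0.31. Lung 2 of 18 months did not share the first 3 rises: its list level was 2.22 for mitosis (1.91 to 2.27 at 10 months), 2.69 for T and NK cells (2.84 to 2.93) and 4.44 for interferon response (4.28 to 4.47). Heart muscle markers were lower (2.04e-10, and 0.415 with an estimated correlation). Their list level was 2.52, 5.36 and 3.61 in KO 1, 2 and 3 of 10 months against 1.89 to 3.47 at 18 months, so the groups overlapped. In all 11 lists passed as higher and 13 as lower. Adipocyte markers were lower at 18 months in WT (adjusted p = 0.0178, and 0.927 with an estimated correlation) and KO (0.0128, and 0.513 with an estimated correlation), but higher without WT 1 of 10 months (0.0119) and without KO 2 of 10 months (0.031).

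Between E19.5 and 10 months in WT the comparison describes maturation of the lung. Proliferation and matrix building gave way to immune and airway genes. Mitosis genes fell, 24 of 24, with Mki67 at −2.70 ± 0.09 (n = 3 per group; list adjusted p = 5.57e-17, and 0.333 with an estimated correlation). Of 17 matrix genes 15 fell and 1 rose, with fibronectin (Fn1) at −3.19 ± 0.13 (1.61e-12, and 0.241 with an estimated correlation). MHC class II genes rose, 9 of 9, with the invariant chain gene Cd74 at 4.67 ± 0.22 (1.2e-15, and 0.241 with an estimated correlation). Jchain, the joining chain of antibodies, rose from 0.0979 ± 0.0356 to 139 ± 17.3 CPM (10.38 ± 0.19, adjusted p = 2.65e-09), and 14 of 15 B and plasma cell genes rose (2.02e-13, and 0.241 with an estimated correlation).

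In this comparison 9801 of 15619 genes were called, 4928 higher and 4873 lower at 10 months, and 3554 at least 2-fold (1832 and 1722). Further large rises were in Mmp3, a matrix metalloproteinase (8.33 ± 0.40), and Bpifa1, an airway secretory protein (9.18 ± 2.41; 6.59 without 10-month WT 1). Sult1d1 was 2224-fold higher (399 to 87893), Cd209f, a lectin, 486-fold (86.8 to 19216), Prmt8, a methyltransferase, 410.0-fold (140.0 to 1991), Capn13, a calpain, at least 57.6-fold and Cd209g at least 52.3-fold. At E19.5 the neuronal gene Dcx was at least 70.7-fold higher, Upk3bl 407-fold (112 to 3365), the noradrenaline enzyme Dbh 317-fold (56.4 to 12568), the myogenic factor Myog 279-fold (49.6 to 11053), the cartilage proteoglycan Acan 241-fold (42.9 to 9582) and the red cell antigen Kel 193-fold (65.8 to 941). WT embryo 3 held 89.7% of the Dbh reads, 85.0% of those of Upk3bl, 76.1% of those of Myog, 68.6% of those of Dcx and 55.6% of those of Acan; without it they were 47.3-fold, 88.0-fold, 96.2-fold, at least 32.1-fold and 155-fold higher. The perinatal myosin Myh8 (−7.19 ± 2.21; −4.60 without WT embryo 3, −9.30 without 10-month WT 3) and the proton pump Atp12a (−7.12 ± 0.50; −8.65 without 10-month WT 3) fell too. Of 13 erythroid genes 13 fell, with the erythroid factor Klf1 at −3.71 ± 0.37 (list adjusted p = 7.94e-06, and 0.361 with an estimated correlation). The adult globin pairs share near-identical sequence, so their single values are uncertain.

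Airway and alveolar genes rose with maturation. All 16 ciliated cell genes rose, Dnah5 by 1.55 ± 0.07 (adjusted p = 8.2e-08, and 0.315 with an estimated correlation), and 9 of 12 alveolar type 1 genes rose, with the water channel Aqp5 at 1.45 ± 0.09 (0.000526, and 0.355 with an estimated correlation). Of 10 club cell genes 4 rose and 1 fell, Scgb1a1 rising by 5.19 ± 0.14 (0.000654, and 0.241 with an estimated correlation). Of 17 retinoid genes 9 rose and 4 fell, with Aldh1a1 at 4.02 ± 0.10 and the retinol acyltransferase Lrat at 5.52 ± 0.18 (0.00382, and 0.361 with an estimated correlation). Of 11 hypoxia genes 9 fell and 1 rose, Ankrd37 standing at −3.37 ± 0.17 (0.000126, and 0.355 with an estimated correlation). In each of these lists the counts adjusted over the list alone were the same. In all 11 lists passed as higher and 8 as lower. Without 1 library these calls were lost, with the adjusted p: Bpifa1 (any WT embryo; 0.101 to 0.103), Dbh and Upk3bl (any 10-month WT; 0.127 to 0.199 and 0.106 to 0.177), Myog (10-month WT 2 or 3; 0.0530 and 0.0790), Myh8 (any 10-month WT or WT embryo 2; 0.0560 to 0.143) and Dcx (WT embryo 1; 0.0673). The groups did not overlap in 10848 genes (69.5%), against 10% by chance.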

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

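The counts over other splits of the libraries were planned, while the 10 tests of the 3 patterns weighed below, and how each is read, were chosen only after the result was seen.

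Of 89 measures examined over the 5 KO non-tumour lungs of 18 months, 12 (13.5%) had 1 lung far from the other 4, with a gap above Dixon's 95% critical value for 5 samples. For normally distributed values chance gives about 1 in 20 such measures, and the measures are not independent of each other. A gene with 1 read in 1 lung and 0 in the others always passes, whatever the lung. Lung 7 stood apart in Xist (832 CPM), the RNA that silences an X chromosome in females, and in the Y-linked genes Kdm5d (0 CPM) and Ddx3y (0 CPM), and so in the list level of sex-linked genes (1.94). It also stood apart in the level of thymus and mediastinal genes (0.555). WT lungs of 18 months lay at 0.550 to 0.581, so lung 7 was within their range. The other KO lungs lay above that range, at 0.659 to 0.698. Lung 6 stood apart in targets of the aryl hydrocarbon receptor, a sensor of aromatic compounds (level 4.07), and in fatty acid oxidation genes (5.34). It also did in Awat1 (0.287 CPM, 10 reads over the 5 lungs) and Cyp21a1 (0.0409 CPM, 1 read). Lung 2 stood apart in glucocorticoid response genes (6.33). Lung 3 stood apart in depth (46.6 M counts, in units of 1e6) and in Gkn2 (0.0220 CPM, 1 read).

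The KO effect at 10 months differed from that at E19.5 for 25 genes by the interaction test. The difference (log2) was 3.53 for Dbp, 1.92 for Hlf, 1.66 for Per3, 1.19 for Nr1d2, 1.08 for Tef, −2.93 for Npas2 and −2.77 for Arntl, which all belong to the clock list. It was −1.51 for the heat shock gene Hsph1 and −0.76 for the co-chaperone Stip1. Further upward differences were Rasd2 1.64, Tspan4 1.55, Wee1 1.10, Cirbp 0.98 and Zfp346 0.70. Further downward ones were Spon2 −2.82, Rasl11a −1.46, Npr3 −1.27, Leo1 −1.24, 5430416O09Rik −1.23, Dtx4 −1.13, Acot1 −1.02, Gprin3 −0.96, Dapk1 −0.72, Glipr2 −0.71 and Fam189a2 −0.61. Of 100 splits 13, the real one included, gave at least 25 genes (highest other 101). Of the 12 others 11 kept the 10-month groups whole and so carry that effect, and the highest that did not keep them gave 29, so no verdict on chance is drawn.

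Clock genes differed between KO and WT lungs at 10 and at 18 months. Different shares of heart muscle in the lung pieces are argued against at 10 months, where 10 of the 10 called clock genes stayed called with the heart muscle level as a covariate, but stay open at 18 months, where that level parts the genotypes (variance inflation 3.46). There 0 of 7 stayed called by edgeR as the SE rose (adjusted p 0.295 to 0.945). All 7 folds stayed over 2 SE from 0, a lower bar than the call. Dbp 3.06 ± 0.25 became 2.98 ± 0.42, and Arntl −2.56 ± 0.22 became −2.93 ± 0.46. Less activity of the Arntl protein would lower its target genes, but 8 of 8 were higher in KO at both ages. This cannot decide the matter, since no label gives a time of day and a phase difference gives the same signs. WT and KO lungs collected at different times of day stay open: 13 of 13 genes of the opposite arms of the clock moved as a phase difference gives at both ages, against 6 of 13 at E19.5, and 0 labels give a time of day; these genes were already seen to move, and a genotype effect on the clock gives the same signs, so the 2 cannot be told apart.

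KO non-tumour lung 7, labelled male, had Xist at 832 CPM and 0 reads over 4 Y-linked genes (Kdm5d, Ddx3y, Uty and Eif2s3y). The other 16 adult libraries had 3285 to 6009 such reads and at most 5.87 CPM of Xist. A swap with another postnatal library of the series is argued against: 0 of 17 postnatal labels name another sex than male, and exchanging male labels gives no female library. RNA of a female animal mixed into a male library is argued against, since 0 Y-linked reads were found. A female animal recorded as male is a candidate explanation (Xist 832 CPM); no biological explanation was tested.

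The globin gene pairs divided their reads differently in tumour 6 and KO non-tumour lungs 6 and 7. Of the alpha-globin reads 0 to 5.85% were given to Hba-a1 in these 3, against 53.6% to 80.1% in the other 20, and the values are uncertain because the paired genes are near-identical. Fewer red blood cells are argued against, since in 3 of 3 the total alpha-globin (2104 to 3927 CPM) lay within the range of the 14 other postnatal libraries (756 to 7737). The gap in this Hba-a1 share was 47.7 percentage points, beyond the width of the others (26.6). The 3 libraries were set apart by the same share, so the gap cannot decide on chance division of the reads by the counting. Globin alleles of another strain in animals 6 and 7 may explain it, as 3 of 3 were also outside all others at the beta-globin pair on another chromosome (Hbb-bs share 71.7% to 85.3% against at most 45.2%); no biological explanation was tested.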

How the results depend on the processing

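Some alternatives were chosen only after the result was seen: the tests with the heart muscle level as a covariate, the tests without KO lungs 6 and 7 together, and the list tests without 1 library.

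With settings other than leaving out 1 library, 96 of 140 counts stayed within 1.5 times the reported one. Of the list results, called or not, 1197 of 1524 stayed on the same side of the threshold, 290 lost and 37 gained a call. Of the named gene results, called or not, 15367 of 16149 did, 491 lost and 291 gained. Results called in neither setting count as staying, so these are no shares of calls kept. No scaling moved the median log2 fold change by over 0.1. Except where given, the cause was not tested.

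DESeq2 called 2 genes at E19.5 (Gm14548, adjusted p = 0.000317, and Rarres1, 0.00522), 594 at 10 months (228 shared with the 233), 154 at 18 months, 3410 for tumour against KO lung, 4182 for tumour against WT, 17 and 11 for age in WT and KO, 1 for the interaction of 18 and 10 months (Gm7120, 0.0200, chosen after its values were seen) and 108 for that of 10 months and E19.5. Rarres1 at 10 months was not called by it. A single fit over all 23 libraries called 1 gene at E19.5 (Rarres1, 0.00286), 41 at 10 months, 26 at 18 months, 5158 and 5417 for tumour against KO and WT, and 6 for the interaction of 10 months and E19.5. On log2(FPKM + 0.1) limma called 2 at E19.5 (Gm14548 and Rarres1, 0.0154) and 142 at 10 months, and on log2(FPKM + 1) 137 at 10 months.

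At 18 months, only lungs 1, 3 and 6 against WT gave 25 genes, only lungs 2 and 7 gave 12 (2 up, 10 down; 4 shared with the 12), a replicate block 8 (4 shared), and the test without lungs 6 and 7 gave 42 (11 shared with the 12). The heart muscle level as a covariate gave 0: edgeR left Dbp at 2.98 ± 0.42 (from 3.06 ± 0.25) and Arntl at −2.93 ± 0.46 (from −2.56 ± 0.22). The calls ended because the SE rose, as the level goes with genotype (variance inflation 3.46). Tumour against KO lung gave 1259 without lungs 6 and 7 (1129 shared with the 2134).

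A replicate block gave 63 genes at 10 months, 146 for tumour against KO lung (145 shared with the 2134), 135 with the 3 matched lungs alone, and 1 each for age in WT (Nrn1, adjusted p = 0.0408) and KO (Marco, 0.0496). Tumours and KO lungs with the same number are read as 1 animal from the labels; in other comparisons the numbers do not pair libraries. Over all comparisons same-number correlations were −0.532 to 0.457, and at most 1 of 3 libraries correlated best with its own number. The block changed the calls of 7 lists for tumour against KO lung: mitosis (0.0563) and MHC class II (0.153) were lost, and B and plasma cells (0.000413), mesenchymal transition genes (0.0471), interferon response (0.00228), glucocorticoid response (0.0445) and sex-linked genes (0.0129) gained. A voom fit with animal number as a random block (correlation 0.115) called 2563 for tumour against KO lung.

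Of the called lists 0 passed with an estimated correlation in each of the 8 comparisons. With fry, over all lists tested, 0 passed at E19.5, at 18 months and with age in WT and KO, 3 at 10 months (2 of the 9 called), 31 from E19.5 to 10 months (19 of the 19), and 17 and 18 for tumours against KO and WT (16 of the 23 and 16 of the 27). At an unadjusted p under 0.01, shared genes were 49 higher and 67 lower in KO at 10 and 18 months, and 1 higher at E19.5 and 10 months (Tmem37, chosen after its values were seen).

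Leaving out 1 library gave 0 to 0 genes at E19.5 by edgeR, 66 to 205 at 10 months, 3 to 26 at 18 months, 1074 to 4066 for tumour against KO lung, 3 to 5722 for tumour against WT, 0 to 10 and 0 to 0 for age in WT and KO, 8885 to 9478 from E19.5 to 10 months, and 0 to 0 and 19 to 31 for the interactions. Called lists numbered 15 to 19 at E19.5 (8 of the 18 shared without KO embryo 3, 9 without WT embryo 3), 7 to 15 at 10 months, 17 to 25 at 18 months, 21 to 26 and 24 to 29 for tumours against KO and WT, 9 to 20 and 18 to 27 for age in WT and KO, and 19 to 20 from E19.5 to 10 months. Of 2568 list results, called or not, 2273 stayed on the same side of the threshold, 159 lost a call and 133 gained one. Lists called in neither fit count among the 2273, so this is no share of calls kept. The direction reversed for skeletal muscle at E19.5 without WT embryo 3 (adjusted p = 0.00146; range 1.987e-06 to 0.543), for adipocytes with age without WT 1 of 10 months (0.0119; range 3.137e-08 to 0.124) and without KO 2 of 10 months (0.031; range 1.801e-08 to 0.102), and for Uty from E19.5 to 10 months without WT embryo 3 (−0.35; range −0.35 to 0.65). That embryo had 1 Y-linked read.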

Other observations

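The counts over other splits of the libraries were planned; the genes named below were chosen after their values were seen.

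Other divisions of the same libraries into groups of the same sizes were tested for each count of genes. For tumour against KO lung, 1 of 56 splits, the real one, gave 2134 genes (highest other 1). Of these splits 8 part the 3 animals with a tumour and a lung as the real one does, while each of the other 7 mixes tumours with lungs; these 8 are too few for a share under 0.05, and the highest other of them gave 0 by edgeR (the real one 2134, DESeq2 3410). At 18 months 2 of 56 gave at least 12, the real one among them. The other gave 32 by setting lungs 1, 6 and 7 against WT with lungs 2 and 3, a structure of the samples. A grouping apart from genotype thus called more genes, so no verdict on chance is drawn. Age in KO gave 0 by edgeR (782 at an unadjusted p under 0.05 where chance gives 773, DESeq2 11). Of its splits 56 of 56 gave at least 0, the highest 31, again with lungs 1, 6 and 7 apart from 2 and 3. The interaction of 18 and 10 months gave 0 by edgeR (453 at an unadjusted p under 0.05 where chance gives 783, DESeq2 1). Most of 100 splits gave 0 too (highest other 1). Every split gives at least 0, so these last 2 counts say nothing about chance. For groups of 3 against 3 the 10 splits are too few for a share under 0.05: the real value and the highest other were 0 and 1 at E19.5, 233 and 2 at 10 months, 2358 and 0 for tumour against WT, 0 and 1 for age in WT, and 9801 and 0 from E19.5 to 10 months.

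WT embryo 3 had Xist at 1259 CPM and 1 Y-linked read, while the other 5 embryos had at most 0.882 CPM of Xist. Its level was 5.31 for basal and squamous genes, 4.02 for skeletal muscle and 2.95 for adipocytes.

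In tumours 1, 3 and 6 the imprinted RNA Meg3 stood at 382, 747 and 384 CPM, and its neighbours at 265, 412 and 123 CPM for Rian, 6.69, 12.0 and 3.34 CPM for Mirg and 57.7, 10.8 and 0.0785 CPM for Dlk1. Nkx2-1 stood at 305, 428 and 293 CPM, Hnf4a at 4.50, 29.1 and 2.75 CPM and Cdkn2a at 8.16, 12.4 and 3.10 CPM. Over 20 chromosomes the median log2 fold change of tumour against KO lung was −0.02 to 0.04. Cyp1a1, a target of the aryl hydrocarbon receptor, stood at 51.1 CPM in tumour 6 and 77.9 CPM in lung 6, against 1.64 to 9.88 CPM in the other adult libraries.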
